A study of Mus musculus with 4 samples.

How the data were processed

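ATAC-seq uses the Tn5 transposase to insert sequencing adapters into accessible DNA, so that fragment ends mark open chromatin. Per the labels' protocols, lamina propria cells were enriched for innate lymphoid cells, ILC1s were sorted by flow cytometry, treated with Tn5 and amplified by PCR. The 4 libraries were grouped by the genotype in the labels, 2 WT and 2 STAT4-KO. The submitters' processing notes list bcl2fastq 2.18.0.12, Trim Galore 0.6.0, Bowtie2 2.3.3.1, Picard 2.9.2, MACS2 2.1.2, HOMER 4.10.3 and the mouse build mm9. The file headers name MACS2 2.1.1.20160309 as the caller that wrote the peak files. Whether reads were shifted for the Tn5 insertion, or mitochondrial or repeat reads removed, is not given in the sources used here, and the mitochondrial genome was called as a peak in every list.

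Peaks were called on each library separately, as read pairs, with a q-value limit of 0.05 and sub-peak summits, per the file headers. Duplicates had been removed from the alignments beforehand, going by the name of the input in the file headers. The option that turns off the local background was set, per the file headers, so each peak was scored against a single genome-wide rate that depends on library depth. In the authors' peak lists the pileup is a signal value, the number of fragments that cover the summit, and it was not scaled to depth. The deposited −log10 p and −log10 q values give the significance of each summit, and the deposited fold enrichment is a ratio of pileup to the background. These scores are the authors' own per-peak values and were used to rank and filter peaks within a list. The authors also deposited 2 tables in which a WT library was called with a STAT4-KO library as control, WT replicate 1 with STAT4-KO replicate 1 and WT replicate 3 with STAT4-KO replicate 2. With the local background turned off, a control library adds nothing local to the score, and each of these tables was identical to the WT list in every summit, position and value. They therefore hold no fold or p-value of genotype.

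Depth was taken as the total number of fragments per library, between 9741037 and 15684721 per the file headers. The lowest pileup called was 7 in the STAT4-KO libraries and 8 in the WT libraries. A region missing from a list may have had fewer fragments than about this number at its summit. Other limits of the caller, such as on peak width, were not examined. Absence from a list does not show closed chromatin. The files list called peaks and not the depth at every region, so no fold change between libraries and no count model was computed.

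Sub-peaks of one interval were joined, and the intervals of the 4 lists were merged wherever they overlapped by at least 1 bp. A merged region was called in a library if any of its peaks overlapped it. Regions called in both libraries of one genotype and in neither of the other were counted and set beside the same counts for the other 2 ways of splitting the 4 libraries into 2 and 2. The smallest exact permutation p of this design is 0.33. Jaccard indices were computed from bases, and shares of peaks from overlaps of at least 1 bp. Shares of single libraries have Wilson intervals at 95% confidence. The regions named in the text were chosen by a rule fixed before the data were examined: the 10 regions per direction with the best rank by the caller's p in the library where they ranked worse, and the 10 best in both comparison tables. The rule asked for the nearest genes and for genes of 13 fixed lists. No gene annotation of mm9 was used here, and the gene table at hand is of the build GRCm38.p6, whose coordinates differ from those of mm9, so regions are named by position and the tests of gene lists and promoters were not run. In their place the chromosomes of genotype-specific regions were tested with two-sided Fisher's exact tests against regions called in all 4 libraries, with Benjamini-Hochberg adjustment over 40 tests, along with windows of 5 Mb and the number of shared regions within 500 kb. These were added after seeing the data.

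The design assumed that the comparison tables might hold values of both genotypes. They hold values of the WT library, so they were only compared with each other and with the peak lists. Alternatives were peaks with a −log10 q of at least 5, an overlap of 50% of the shorter interval, lists reduced to the 24385 best peaks by p, intervals of 200 bp on each side of the summit, the sex chromosomes and unplaced sequences left out, and each library left out in turn. Added after seeing the data were a minimum pileup of 1.5 or 2 times the lowest call of the absent libraries, scaled by total fragments or by the median pileup of regions called in all 4 libraries, each library pair alone, and overlaps outside the library pairs. The merging and counting were tested on 5000 simulated regions, where 524 of 524 simulated WT-only and 311 of 311 simulated STAT4-KO-only regions were recovered. The exact test gave a p under 0.05 in 30 of 1000 simulated tests with no difference and in 947 of 1000 with a 3-fold share. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.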

Results

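Chromatin accessibility was profiled by ATAC-seq in type 1 innate lymphoid cells (ILC1s) sorted from the lamina propria of the mouse colon. ILC1s are tissue-resident lymphocytes that resemble natural killer cells and produce interferon-γ. The labels give colonic lamina propria as the tissue, and their protocol describes isolation from both colon and small intestine. The cells were sorted as lineage-negative cells carrying Thy1.2, CD127, NK1.1 and NKp46. The cells came from wild-type (WT) C57BL/6 mice and from mice lacking STAT4, a transcription factor activated downstream of the interleukin-12 receptor. The series holds 4 libraries, 2 of each genotype: WT replicates 1 and 3, and STAT4-knockout (STAT4-KO) replicates 1 and 2. The labels do not say whether the libraries of a genotype came from different animals, so differences between them may be technical. The comparison addresses which accessible regions differ between ILC1s with and without STAT4.

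In WT replicate 1, 38825 peak intervals covered 43.2 Mb, and in WT replicate 3, 30795 intervals covered 27.6 Mb. In STAT4-KO replicate 1, 37156 intervals covered 39.6 Mb, and in STAT4-KO replicate 2, 24385 intervals covered 20.6 Mb. Over the 4 libraries, the number of peaks did not follow the total number of fragments. WT replicate 3 was the deepest library, with 15684721 fragments for 30795 peaks. STAT4-KO replicate 1 was the shallowest, with 9741037 fragments for 37156 peaks. WT replicate 1 had 13668746 fragments and STAT4-KO replicate 2 had 11547363. Both WT libraries thus had more fragments than both STAT4-KO libraries, so depth by total fragments differed together with genotype. The fragment size was 307 bp in WT replicate 1 and 309 bp in STAT4-KO replicate 1, against 236 bp in WT replicate 3 and 256 bp in STAT4-KO replicate 2. These are also the library pairs that the authors set against each other, called here the first and the second pair.

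**Figure D1:**
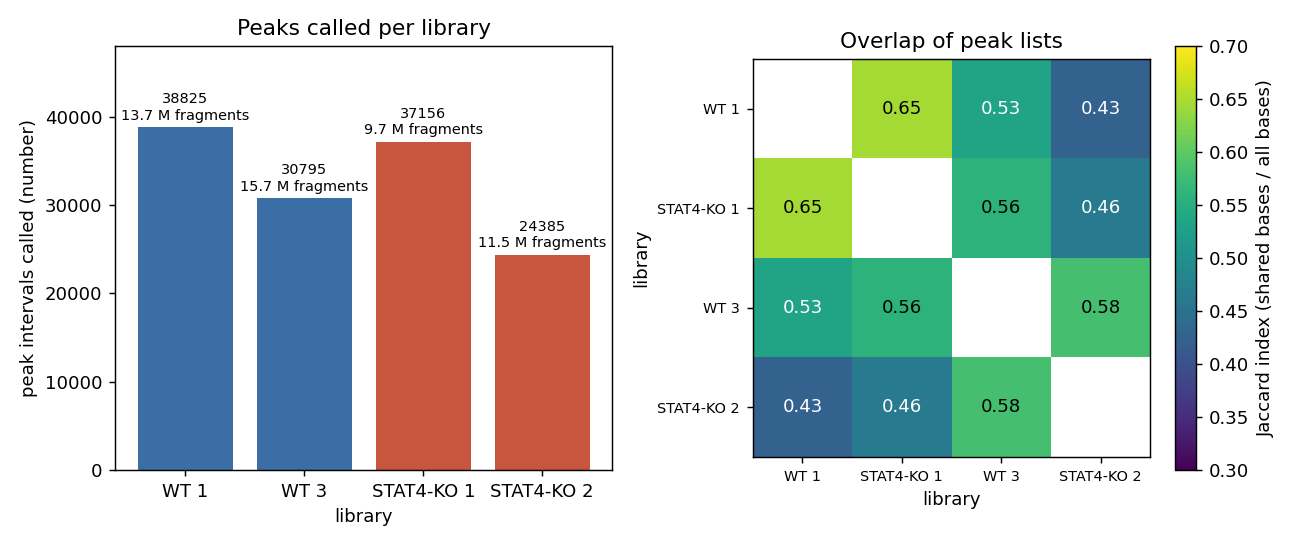
Left, number of peak intervals called in each library, with its total fragments above the bar, for WT (blue) and STAT4-KO (red). Right, Jaccard index of each pair of peak lists (bases covered in both over bases covered in either), from 0.43 for WT 1 with STAT4-KO 2 to 0.65 for WT 1 with STAT4-KO 1.

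The 10 regions that ranked highest in both WT libraries were all called in both STAT4-KO libraries. The highest summit lay on chromosome 2 at 98506387–98507496 (mm9), with a pileup of 32114 fragments in WT replicate 1, 30629 in WT replicate 3, 28524 in STAT4-KO replicate 1 and 27856 in STAT4-KO replicate 2. The mitochondrial genome (positions 1–16299) was called as a single region, with summit pileups of 24067 and 20493 in the WT libraries and 20910 and 27488 in the STAT4-KO libraries. The others included chromosome 9 at 2999990–3038338 and chromosome 1 at 24618371–24623026, with pileups between 18002 and 24125 over the 4 libraries. Pileups are raw fragment depths that were not scaled to library size, so they describe each list and are not compared between libraries. These 10 regions include the mitochondrial genome and unplaced sequence, and their pileups are far above the library medians of 18 to 32, so they are not a measure of shared open chromatin.

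The 4 peak lists merged into 50253 regions. Of these, 19367 (38.5%) were called in all 4 libraries, with a median width of 1462 bp. At these shared regions the median summit pileup was 78 in WT replicate 1, 33 in WT replicate 3, 42 in STAT4-KO replicate 1 and 22 in STAT4-KO replicate 2. A further 5777 regions were called in 3 libraries and 6810 in 2. The remaining 18299 regions (36.4%) were called in a single library, 7448 of them in WT replicate 1 and 6460 in STAT4-KO replicate 1.

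The comparison of genotypes asked which regions were called as peaks in both libraries of one genotype and in neither library of the other. This held for 1264 WT-only regions, which made up 5.02% of the 25198 regions called in both WT libraries. It held for 221 STAT4-KO-only regions, 1.06% of the 20798 called in both STAT4-KO libraries. The WT-only regions were narrow, with a median width of 594 bp, and low, with a median pileup of 16 in WT replicate 1 and 11 in WT replicate 3. The STAT4-KO-only regions had a median width of 829 bp and median pileups of 11 and 9 in STAT4-KO replicates 1 and 2. The lowest pileup that was called at all was 8 in each WT library and 7 in each STAT4-KO library. Where every list was reduced to its best 24385 peaks, the counts were 501 WT-only and 406 STAT4-KO-only regions. Without STAT4-KO replicate 2 the order of the counts turned around, with 1471 WT-only and 6686 STAT4-KO-only regions. In that setting a STAT4-KO-only region needs a call in 1 library and a WT-only region in 2, so the counts are not comparable.

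The WT-only region that ranked best in both WT libraries lay on chromosome 1 at 24740864–24741401, where the summit pileup was 216 in WT replicate 1 and 74 in WT replicate 3. Scaled by total fragments to STAT4-KO replicates 1 and 2, the pileup of WT replicate 3 would be 46.0 and 54.5, and scaled by the median pileup of shared regions 94.2 and 49.3, against a lowest call of 7 in both. Over the 10 best-ranked regions, the pileup of WT replicate 3 scaled to STAT4-KO replicate 1 ranged from 11.2 to 46.0 by total fragments and from 22.9 to 94.2 by shared regions. Scaled to STAT4-KO replicate 2, it ranged from 13.3 to 54.5 and from 12.0 to 49.3. The second lay on chromosome 13 at 85538043–85539195, with pileups of 164 and 64 in WT replicates 1 and 3. The third, on chromosome 1 at 102076677–102076987, had pileups of 71 and 66. The region on chromosome 6 at 146134070–146134650 had pileups of 82 and 26, and that on chromosome 4 at 154956157–154957041 had 55 and 26. The next regions by rank were on chromosome 14 at 69874976–69875829, chromosome 17 at 34822507–34823224, chromosome 9 at 63563807–63564269, chromosome 19 at 5817683–5818432 and chromosome 5 at 136387572–136388258. Their pileups were between 44 and 59 in WT replicate 1 and between 18 and 23 in WT replicate 3. All 10 of these regions remained WT-only at a −log10 q of at least 5 and with lists of equal length. That outcome was fixed by how the regions were chosen. Their −log10 q was at least 9.9 in both WT libraries, and their worse rank was at most 16229, within the reduced lists. Both settings only remove peaks, so neither could add a STAT4-KO call. The 2 settings therefore do not test these regions. Regions are given by mm9 position, because no gene annotation of that build was used here, and the Stat4 locus itself was not analysed here.

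The best-ranked STAT4-KO-only region lay on chromosome 13 at 91222071–91222972, with a summit pileup of 47 in STAT4-KO replicate 1 and 28 in replicate 2. Scaled by total fragments to WT replicates 1 and 3, the pileup of STAT4-KO replicate 2 would be 33.1 and 38.0, and scaled by shared regions 99.3 and 42.0, against a lowest call of 8 in both. For 6 of the 10 best-ranked regions, the pileup of STAT4-KO replicate 2 scaled to WT replicate 1 was 11.8 by total fragments and 35.5 by shared regions. Scaled to WT replicate 3, it was 13.6 and 15.0. The region on chromosome 5 at 15882567–15884021 had pileups of 28 and 15, and that on the X chromosome at 5456018–5456482 had 25 and 14. The regions on chromosome 10 at 8269502–8270885 and chromosome 2 at 57074111–57075784 were high in STAT4-KO replicate 1, with pileups of 52 and 65, and had a pileup of 10 each in STAT4-KO replicate 2. The next were on chromosome 9 at 52692527–52694727, the X chromosome at 44789193–44790634, chromosome 16 at 75305764–75307914, chromosome 9 at 15412488–15413392 and chromosome 10 at 35029898–35030871. Their pileups were between 19 and 21 in STAT4-KO replicate 1 and between 10 and 14 in replicate 2. With only peaks at a −log10 q of at least 5, 4 of these 10 regions remained STAT4-KO-only.

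**Figure D2:**
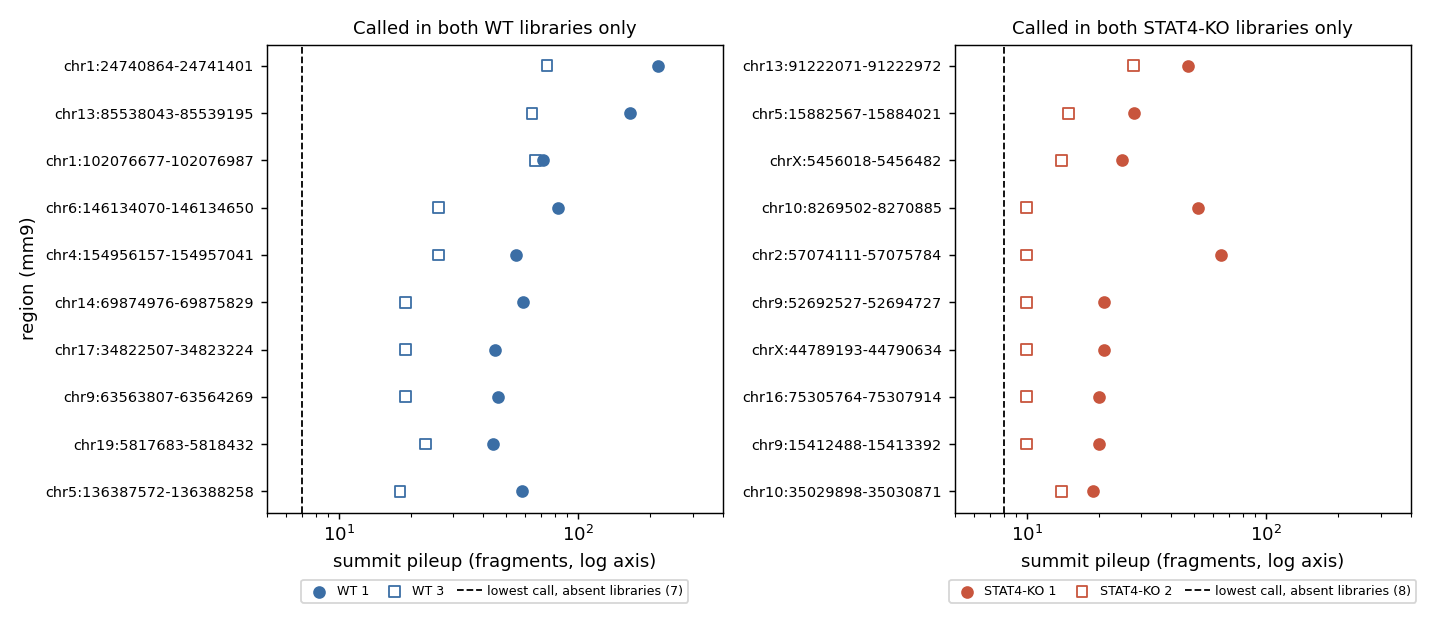
Summit pileup (fragments, log axis) of the 10 best-ranked regions called in both WT libraries only (left, blue) and in both STAT4-KO libraries only (right, red), by mm9 position. Circles are replicate 1 of each genotype, squares are WT replicate 3 and STAT4-KO replicate 2, and the dashed line is the lowest pileup called in the libraries that lack the region (7 and 8). WT-only regions reach 216, and 6 of the STAT4-KO-only regions sit at 10 in STAT4-KO replicate 2.

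More regions parted the library pairs than the genotypes. In all, 1485 regions were called in both libraries of one genotype only, and 4623 were called in both libraries of one pair only. Of the latter, 4387 belonged to the first pair and 236 to the second. The remaining way of splitting the libraries, WT replicate 1 with STAT4-KO replicate 2 against WT replicate 3 with STAT4-KO replicate 1, gave 702 regions, 254 and 448. With lists of equal length the order was the same, at 907 regions by genotype, 1762 by pair and 666 by the crossed split. The 4 libraries allow 3 such splits, so an exact permutation test cannot give a p below 0.33, and the count by genotype ranked second of the 3.

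**Figure D3:**
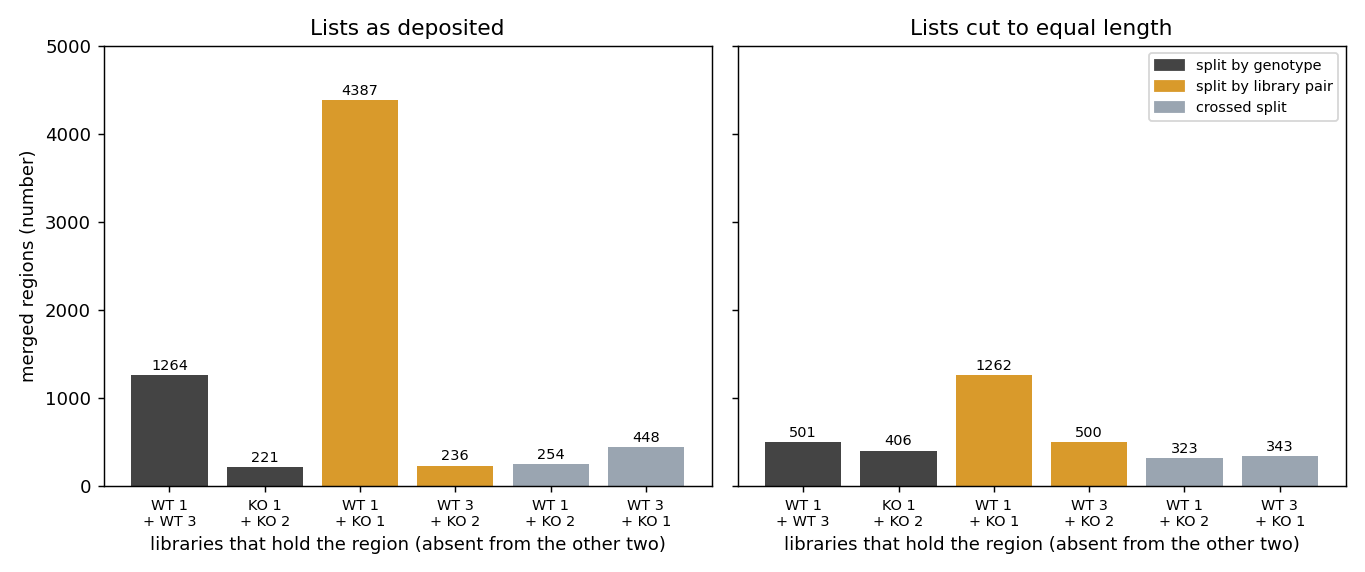
Number of merged regions called in exactly the 2 libraries named under each bar, for the lists as deposited (left) and the lists reduced to equal length (right). Dark bars follow the genotype (1264 and 221 as deposited), orange bars the library pair (4387 and 236) and grey bars the crossed split (254 and 448).

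Within the first pair, 29092 regions were called in both genotypes, 9171 in WT and not in STAT4-KO, and 7363 in STAT4-KO and not in WT, a ratio of 1.25. Within the second pair, 20042 regions were called in both, 9095 in WT and not in STAT4-KO, and 2821 in STAT4-KO and not in WT, a ratio of 3.22. Of the regions present in WT and absent in STAT4-KO in one pair, 13.8% of those of the first pair and 13.9% of those of the second were found with the same pattern in the other pair. For regions present in STAT4-KO and absent in WT, the shares were 3.0% and 7.83%. Over all 50253 merged regions, the same pattern in the other pair was more frequent than this in every case. The merged regions include those called in a single pair and none that all 4 lists lack, which raises that frequency. These shares therefore decide neither for nor against recurrence between the pairs. Of regions called in exactly 1 library of each pair, 1264 and 221 differed in the same direction in both pairs. In opposite directions there were 254 and 448. These counts also depend on list length and were not tested by pair.

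The bases covered by the peak lists gave the same order of similarity. The Jaccard index was 0.534 between the WT libraries and 0.465 between the STAT4-KO libraries. It was 0.646 within the first pair and 0.582 within the second, and 0.426 and 0.558 in the remaining comparisons across genotype. The mean was 0.499 for libraries of the same genotype and 0.553 for libraries of different genotype. Without the library pairs, the mean for different genotype was 0.492, so the difference of -0.0539 rested on the pairs. Both same-genotype values lay within the range of the 4 values across genotype. A Jaccard index cannot exceed the shorter covered length over the longer. Covered lengths were 43.2 and 39.6 Mb in the first pair and 27.6 and 20.6 Mb in the second. They were 43.2 and 27.6 Mb for the WT libraries and 39.6 and 20.6 Mb for the STAT4-KO libraries. Unequal lengths could thus give this order, so it is not separate evidence of likeness within pairs. By intervals, 76.3% of the peaks of WT replicate 1 overlapped a peak of its pair mate STAT4-KO replicate 1 and 65.7% a peak of WT replicate 3, but 86.9% of the peaks of WT replicate 3 overlapped WT replicate 1 and 67.9% its pair mate STAT4-KO replicate 2. In both cases the higher share was with the longer list.

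The authors' deposited tables of WT against STAT4-KO held no further contrast between the genotypes. In the authors' deposited table for the first pair, all 48539 summits had the position and values of the WT replicate 1 list. In the authors' deposited table for the second pair, all 37997 summits had those of the WT replicate 3 list. A total of 25394 regions were present in both of the authors' deposited tables, and these are regions of WT accessibility whether or not they were open in STAT4-KO cells.

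The genotype-specific regions were not spread over the chromosomes as the shared regions were. Of the 219 STAT4-KO-only regions on chromosomes 1 to 19 and X, 24 (11%) lay on the X chromosome, against 2.69% of regions called in all 4 libraries (odds ratio 4.46, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 4.6e-07 over 40 tests). With only peaks at a −log10 q of at least 5, the share was 6.45% and did not pass (Fisher's exact test, unadjusted p = 0.069). The X chromosome also held 9.47% of the regions called in STAT4-KO replicate 1 alone and 10.7% of those shared by STAT4-KO replicate 1 and WT replicate 3 only. It held 1.09% of those in STAT4-KO replicate 2 alone and 1.27% of those shared by STAT4-KO replicate 2 and WT replicate 3 only. The share of STAT4-KO-only regions on X was 4.56% without WT replicate 1 and 5.08% without STAT4-KO replicate 1. Of the 1261 WT-only regions, 112 (8.88%) lay on chromosome 11, against 6.06% of regions in all 4 libraries (odds ratio 1.51, Fisher's exact test, adjusted p = 0.0029). Chromosome 11 held 9.06% of the regions that were missing from STAT4-KO replicate 2 alone. The excess on chromosome 11 was lost without WT replicate 1 (5.93%) and without WT replicate 3 (6.30%). On chromosome 1, the shares were 7.14% of WT-only and 9.13% of STAT4-KO-only regions, against 6.85% of shared regions, and neither passed the test (Fisher's exact test, adjusted p = 0.93 and 0.81). Regions are not replicates, so these p-values describe the 4 libraries and not the genotypes, and the chromosome test was chosen after seeing the data.

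Peaks on the Y chromosome were found almost entirely in the STAT4-KO libraries. On the assembled Y chromosome, STAT4-KO replicate 1 had 6 peaks and STAT4-KO replicate 2 had 12, and the WT libraries had 0. On sequence assigned to the Y chromosome but not placed on it, the counts were 35 and 747 in STAT4-KO replicates 1 and 2, 0 in WT replicate 1 and 1 in WT replicate 3. Other unplaced sequences held 207 and 218 peaks in the STAT4-KO libraries and 198 and 293 in the WT libraries. Only 1 of the 800 merged Y regions was called in both STAT4-KO libraries. The X chromosome held 4.26% of the peaks of STAT4-KO replicate 1 (95% Wilson interval 4.05 to 4.47%) and 2.68% of those of STAT4-KO replicate 2 (2.49 to 2.89%), against 2.98% (2.81 to 3.15%) and 3.22% (3.03 to 3.42%) in WT replicates 1 and 3. These intervals cover counting error only. Without the X and Y chromosomes and unplaced sequences, 1223 WT-only and 195 STAT4-KO-only regions were left. The labels do not give the sex of the animals.

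**Figure D4:**
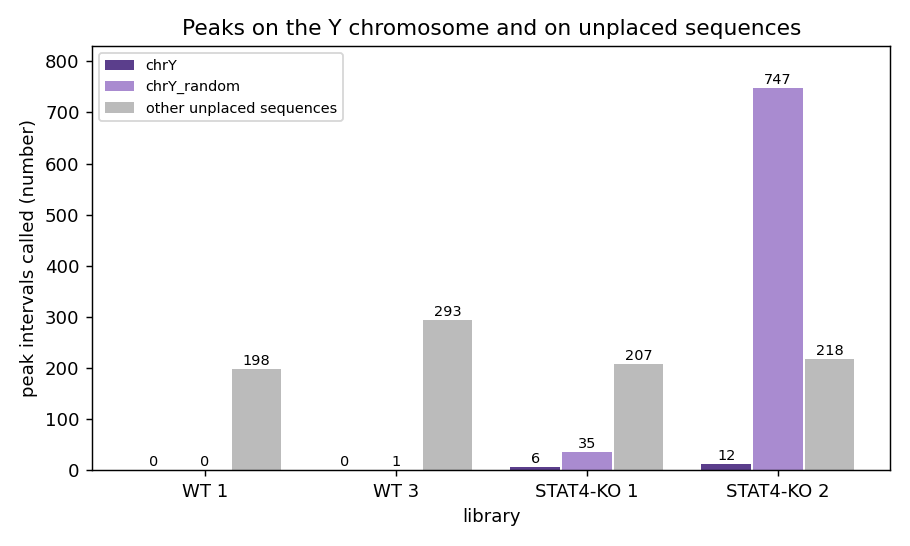
Number of peak intervals on the assembled Y chromosome (chrY, dark), on unplaced sequence of the Y chromosome (chrY_random, light) and on other unplaced sequences (grey) in each library. The STAT4-KO libraries have 6 and 12 peaks on the assembled Y chromosome and the WT libraries have 0.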

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

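The pileup minimum with its scalings, the single pairs, the comparisons outside the pairs and the chromosome shares were added after seeing the data; the other settings were fixed before the data were examined. The counts of WT-only and STAT4-KO-only regions moved by less than 1.5 times with an overlap of 50% (1232 and 206), with 200 bp around summits (1726 and 293) and without the X and Y chromosomes and unplaced sequences (1223 and 195). At a −log10 q of at least 5 they fell to 794 and 63. With lists of equal length the WT-only count fell to 501 and the STAT4-KO-only count rose to 406. They fell to 292 and 14 where presence needed a −log10 q of at least 5 and absence was judged from the full lists. A pileup of at least 1.5 times the lowest call of the absent libraries left 80 and 41 when scaled by total fragments and 20 and 33 when scaled by the median pileup of shared regions, and of 2 times 13 and 8 or 5 and 3. By either scaling, most of these regions were under 1.5 times the limit in at least 1 absent library. The same minimums left 3084 and 1563 regions that part the library pairs by total fragments, and 290 and 154 by shared regions. With a library left out, fewer lists must meet the condition, and the counts ranged from 1471 (without STAT4-KO replicate 2) to 8735 (without WT replicate 3) for WT-only and from 454 (without WT replicate 3) to 6686 (without STAT4-KO replicate 2) for STAT4-KO-only regions. Without WT replicate 1 they were 4402 and 1237, and without STAT4-KO replicate 1 they were 5700 and 1615. WT-only regions were the more numerous in all of these settings except without STAT4-KO replicate 2 and at 1.5 times the limit scaled by shared regions. With a library left out the order is not informative, because the genotype that lost it needs 1 call and the other needs 2. The first pair alone gave 9171 and 7363, and the second 9095 and 2821. Regions in both comparison tables numbered 20634 at the stricter q and 25259 at 50% overlap, and a single table held 30795 or 38825. Over all 4 comparisons across genotype, the Jaccard index stayed lower within than between genotypes under the stricter q (-0.0670), equal lengths (-0.0494) and summit intervals (-0.0154), and the share of intervals at 50% overlap was lower by the same sign (-0.70 percentage points). Against the comparisons across genotype outside the library pairs, the difference changed sign (0.0071), since the pairs hold the highest indices. The share of WT-only regions on chromosome 11 ranged from 5.93% to 9.03% with a library left out and fell below that of shared regions without WT replicate 1; the cause was not tested. The share of STAT4-KO-only regions on the X chromosome was 6.45% at the stricter q, where it no longer passed the exact test, and 4.56% to 9.64% with a library left out. No paired analysis was possible by replicate number, because the genotypes share only 1. Within the authors' 2 library pairs, the ratio of regions called in WT alone to regions called in STAT4-KO alone was 1.25 and 3.22, and was not tested. The direction was fixed by list length, since the WT library held more merged regions in each pair (38263 against 36455, and 29137 against 22863). The tests of 13 gene lists and of promoters, with their alternatives, were not run, since no annotation of mm9 was used here. Fold thresholds on the comparison tables and count models do not apply to peak lists without counts.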

Other observations

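All tests on region surroundings, windows and Y peaks were chosen after the results were seen, and so were the tests of depth, fragment size, the calling limit and the loss of STAT4; the 2 tests with lists of equal length were stated before their own results were seen, the one on library pairs after the count by pair was known.

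WT-only regions lay in stretches of the genome that were rich in regions called in all 4 libraries, and STAT4-KO-only regions did not. On the autosomes, WT-only regions had a mean of 15.3 ± 8.60 (SD, n = 1223) shared regions within 500 kb, and STAT4-KO-only regions had 7.30 ± 7.89 (SD, n = 195). The difference was 7.99 (two-sided permutation p = 2e-05, the smallest that the resamples can give). Regions are not replicates, and the other 2 splits of the libraries also differed, by 4.01 for the library pairs and 2.79 for the crossed split. The low density was not particular to the STAT4-KO-only regions. The median was 5 for them, 5 for regions called in STAT4-KO replicate 1 alone, 5 for those in STAT4-KO replicate 2 alone and 4 for those missing from WT replicate 1 alone, against 14 for regions in all 4 libraries. Nor was the high density particular to WT-only regions, whose median was 14. It was 14 for regions in WT replicate 1 alone and 14 for those of the first pair only. For regions shared by WT replicate 1 and STAT4-KO replicate 2 only it was 12. Without WT replicate 1, it was 12 for regions in WT replicate 3 alone and 8 for those of the second pair only.

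Among 541 windows of 5 Mb with at least 20 regions each, 2 passed a test for an excess of WT-only regions, both on chromosome 11. At 115 to 120 Mb, 18 of 223 regions (8.07%) were WT-only, against 2.52% overall (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0088). At 95 to 100 Mb, 15 of 189 regions (7.94%) were WT-only (exact test, adjusted p = 0.026). At 85 to 90 Mb the share was 8.80% (11 of 125) and did not pass (exact test, adjusted p = 0.06). The window with the lowest p for STAT4-KO-only regions, chromosome 5 at 55 to 60 Mb, held 3 of 27 regions and did not pass (exact test, adjusted p = 0.12, unadjusted p = 0.00023). Regions called only in the second library pair passed the same test in 8 windows. The strongest were unplaced sequences, of chromosome 1 with 22 of 108 regions (20.4%) and of chromosome 8 with 18 of 97 (18.6%). Next came chromosome 8 at 15 to 20 Mb with 20 of 152 regions (13.2%) and chromosome 5 at 10 to 15 Mb with 14 of 79 (17.7%).

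More regions were WT-only than STAT4-KO-only, 1264 against 221. The order turned around at a pileup of at least 1.5 times the lowest call of the absent libraries, scaled by shared regions (20 against 33). With every list reduced to the same length, the ratio of WT-only to STAT4-KO-only regions was 1.23 (95% exact binomial interval 1.08 to 1.41). Unequal list lengths may therefore account for most of the excess. The lists were not longer by genotype throughout, with 37156 peaks in STAT4-KO replicate 1 against 30795 in WT replicate 3. STAT4-KO replicate 2 had the shortest list, with 24385 peaks. From it alone 4362 regions were missing, against 205 from STAT4-KO replicate 1, 976 from WT replicate 3 and 234 from WT replicate 1 alone. Only 1.03% of WT-only regions (0.549 to 1.75%) had summits at least 2 times the limit of the absent libraries when scaled by total fragments. When scaled by shared regions the share was 0.396% (0.129 to 0.921%). Each WT summit had to pass against each STAT4-KO library, so 1 weak pairing was enough to fail. By the same rule, 8 of the 221 STAT4-KO-only regions passed by total fragments and 3 by shared regions. Summits near the calling limit may thus have been missed in some libraries. STAT4-KO-only regions mostly failed too. The regions that passed were closer in number than 1264 and 221, at 13 WT-only and 8 STAT4-KO-only by total fragments. By shared regions they were 5 and 3. Missed calls near the limit may therefore account for part of the excess of WT-only regions, but so few regions cannot settle how much. At equal length, regions that part the genotypes numbered 1.36 times those of the crossed split (907 against 666, interval 1.23 to 1.51), and the highest other split had 1762. The intervals of these ratios and shares cover counting error only. With 3 splits of 4 libraries, a share under 0.05 cannot be reached, and an effect of the loss of STAT4 cannot be told apart from differences between the libraries. Both WT libraries also had more total fragments than both STAT4-KO libraries, so depth cannot be told apart from genotype either.

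More regions parted the library pairs than the genotypes, 4623 against 1485. At a pileup of at least 1.5 times the lowest call of the absent libraries, 3084 regions parted the pairs by total fragments. Scaled by shared regions, 290 did, against 20 WT-only and 33 STAT4-KO-only regions. The first pair did not have more total fragments: its WT library had 0.871 times and its STAT4-KO library 0.844 times those of the second. Total fragments therefore do not account for the pattern, but they do not measure depth at peaks. At regions called in all 4 libraries, the median pileup was 78 (WT) and 42 (STAT4-KO) in the first pair, against 33 and 22 in the second. Deeper coverage of open regions in the first pair is therefore not excluded. Longer peak lists of the first pair are not the whole cause, since with equal lengths the pairs still parted 1.94 times as many regions as the genotypes (1762 against 907, interval 1.79 to 2.11). That interval covers counting error only. A library preparation shared within a pair remains open as a hypothesis: fragment sizes differed by at least 51 bp between pairs and by at most 20 bp within them. The labels give no batch, so this explanation cannot be told apart from other differences between the pairs.

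Peaks on the Y chromosome were found in both STAT4-KO libraries and, but for 1 peak on unplaced sequence, not in the WT libraries. Reads that fall on unplaced or repeated sequence in general do not account for this, since peaks on other unplaced sequences in STAT4-KO were 0.744 times those in WT in the second pair (95% exact binomial interval 0.621 to 0.890, counting error only) and 1.05 times in the first (0.856 to 1.28). In the second pair, 12 peaks on the assembled Y chromosome in STAT4-KO against 0 in WT go with male cells in the STAT4-KO library and none in the WT library. The share of peaks on X was 2.68% against 3.22%, not above that of WT, as this hypothesis also asked. That share adds little, since it can fall with a shorter list. The X chromosome held 2.67% of regions called in all 4 libraries and 4.47% of those in WT replicate 3 alone. In the first pair the counts were 6 and 0, but STAT4-KO replicate 1 had only 41 Y peaks in all against 759 in replicate 2, and its X share was above that of WT replicate 1 (4.26% against 2.98%), so male cells in this library stay open. If the hypothesis holds for a pair, sex and genotype differ together in it, and leaving out X, Y and unplaced sequences (1223 WT-only and 195 STAT4-KO-only regions) says nothing of effects of sex on the autosomes.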
